A study of Mus musculus with 9 samples.

How the data were processed

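The values analysed were the deposited expected counts per gene, 1 set for each of 9 libraries of left ventricle RNA. About 27.6% of the deposited values were not whole numbers and 81.2% lay within 0.01 of a whole number, and the totals differed between libraries, so they were read as counts of the expected kind, not scaled between libraries. The submitters' processing notes name bcl2fastq, STAR and Partek and the build mm10, and give no version or role for any tool, and the counting rule is not given in the sources used here. The values cover 20634 genes, 156 of them at 0 in every library, and no gene of the mitochondrial chromosome. A set of 8 pseudogenes (Gm13340, Gm28437, Gm29216, Gm28661, Gm10925, Gm28439, Gm11410 and Gm13339) held 19.8% to 28.6% of the counts of a library and Gm42418 held 2.13% to 3.50%, and all were kept. Coordinates are those of the deposited annotation, with 1 subtracted from the end, since 15571 of the 19704 symbols shared with GENCODE M21 then had the same start and end, against 70 before.

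Libraries were grouped by title and source name into WT vehicle, WT ifetroban, KO vehicle and KO ifetroban. Expected counts were rounded, genes were kept with filterByExpr on group (minimum count 10), which left 15549, and libraries were scaled with TMM factors. Depth per library was 21510263 to 30182955 counts, and the common biological coefficient of variation was 0.176. The quasi-likelihood test of edgeR 4.0.16 (robust dispersion and robust fit, R 4.3.3) was applied to a model with 4 group means for genotype under vehicle, genotype under ifetroban, ifetroban in KO, ifetroban in WT and their interaction, and to an additive model of genotype and treatment for each effect over the other factor. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in a comparison, with a threshold of 0.05. SE values are the log2 fold change divided by the square root of the F statistic, and CPM are TMM-scaled. The log2 CPM used for the length slope had a prior count of 2. Transcript length and GC content were those of the longest GENCODE M21 transcript of a symbol, found for 96.1% of the tested genes.

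Gene lists, 29 with 706 entries (698 distinct genes), were fixed before the data were examined, and 639 entries were tested. The 26 lists with at least 5 tested genes were tested with camera from limma 3.58.1 at a preset correlation of 0.01, and also with an estimated correlation and with fry, adjusted over the lists of a comparison. Of the other lists, the skeletal muscle one had 3 tested genes, with 0 changed in any comparison and a median log2 change of -0.40 for genotype under vehicle, 2.50 for genotype under ifetroban, 0.96 for genotype over both treatments, 1.89 for ifetroban in KO, -0.53 for ifetroban in WT, 1.04 for ifetroban over both genotypes and 2.32 for the interaction. The sex-linked one had 4 (medians from -0.31 under vehicle to 0.14 for ifetroban in KO, 0 changed) and the mitochondrially encoded one 0. The groups, comparisons, tests, lists and the rule for named genes were also chosen before the data were examined. By that rule Sgcd comes first. For each comparison the genes named are up to 8 rises and 8 falls with the largest fold change among those past the threshold with a mean of at least 1 CPM and, outside the interaction and the additive models, no overlap between the groups, leaving out predicted-gene symbols. Where fewer than 5 genes pass, the 3 with the smallest p in each direction are named as not passing. Up to 3 passing members of each list with the smallest adjusted p are named, or 2 members as values where a list passes without any (only for genotype under vehicle, genotype over both treatments and ifetroban in KO), and Tbxa2r, Nppa, Nppb and Myh7 are named always. Ttn, Ryr2, Xist, Ddx3y and Gm12167 were named outside the rule, after their values were seen.

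Alternatives chosen in advance were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, no low-count filter, a stricter filter (1 CPM in every library of a group), only the groups compared, replicate number as a block, KO ifetroban replicate 1 counted as vehicle, a 2-fold minimum and each library left out in turn. Chosen after seeing the data were the split by length slope as a term, the libraries of each slope alone, an offset from splines (4 degrees of freedom) on transcript length and GC content, and protein-coding genes only. The opposite-effect covariance was set beside 100 simulations of unchanged groups. The number of genes past the threshold in the additive models was set beside 100 of the 126 splits of the libraries into 5 and 4, the real one included.

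Each step was tested on simulated counts with 200 changed genes among 15549. For genotype under vehicle 51% of genes changed by 1 on the log2 scale and 88% of those changed by 2 were recovered, with 3 false calls. For ifetroban in KO these were 58% and 85%, with 10 false calls, and for genotype over both treatments 72% and 92%, with 13 false calls. A list shifted in each simulation passed, and 0 other lists did. Genes were drawn independently of each other there, so this does not test false list calls among correlated genes. The simulated counts also held no length-slope structure, so recovery in the data may differ from these percentages. In the data the estimated correlation was 0.845 for oxidative phosphorylation genes under vehicle. For opposite effects a simulated covariance of -0.0375 was recovered as -0.0343 over 13436 genes.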

Results

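RNA-seq was carried out on 9 left ventricle samples from wild-type (WT) and delta-sarcoglycan knockout (KO) mice on a C57BL/6 background. Delta-sarcoglycan, the product of Sgcd, belongs to the dystrophin-associated complex of the muscle cell membrane, and mice without it develop muscular dystrophy with cardiomyopathy. Animals drank plain water (vehicle) from weaning, or water that delivered ifetroban, an antagonist of the thromboxane-prostanoid receptor, at 25 mg/kg/day. Running wheels were given at intervals, and hearts were collected at 6 months of age. The design crossed genotype with treatment, with 2 WT vehicle, 2 WT ifetroban, 2 KO vehicle and 3 KO ifetroban libraries. Total counts were 21648094 and 24302832 for WT vehicle, 25337805 and 23831042 for WT ifetroban, 25936623 and 25342316 for KO vehicle, and 21510263, 30182955 and 23177801 for KO ifetroban. Between 18548 and 19199 genes had a count in each library, and 15549 genes were tested. Replicates differed by more than counting noise, with a chi-square per degree of freedom between 10.99 and 65.4. The labels do not state that replicates came from separate animals, so every p-value measures only the spread between these samples. The labels of KO ifetroban replicate 1 conflict, since its title and source name give ifetroban and its treatment characteristic gives vehicle, and it was analysed as ifetroban. All 9 libraries had at most 2 counts of Xist, the transcript that silences the X chromosome in females, and at least 1371 counts of the Y-linked gene Ddx3y.

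The libraries fell into a pair of sets that did not follow the groups. Across 13051 protein-coding genes, a gene's deviation from its mean over libraries fell with transcript length in 4 libraries and rose with it in the other 5. Spearman's rho across genes, which are not independent replicates, was -0.46 for the library labelled WT vehicle replicate 1, -0.40 and -0.45 for KO vehicle, and -0.52 for KO ifetroban replicate 1. It was 0.41 for WT vehicle replicate 2, 0.43 for each WT ifetroban library, and 0.40 and 0.38 for KO ifetroban replicates 2 and 3. With the 4 groups in the model, 4242 genes differed between the sets (edgeR, adjusted p under 0.05), 2291 of them higher in the positive-slope set. The sets were drawn from the same values, so this count gives the size of the split and is no separate test of it. The giant sarcomere gene Ttn differed by 0.90 and the ryanodine receptor gene Ryr2 by 1.00 on the log2 scale. Neither KO vehicle library had a positive slope and neither WT ifetroban library had a negative one. A genotype value within the negative-slope set is therefore genotype under vehicle, and within the positive-slope set genotype under ifetroban, while an ifetroban value is that in KO and in WT, and none of them estimates an effect over both. Values within the sets are printed for Sgcd, for counts of genes and for some of the lists and genes.

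**Figure D1:**
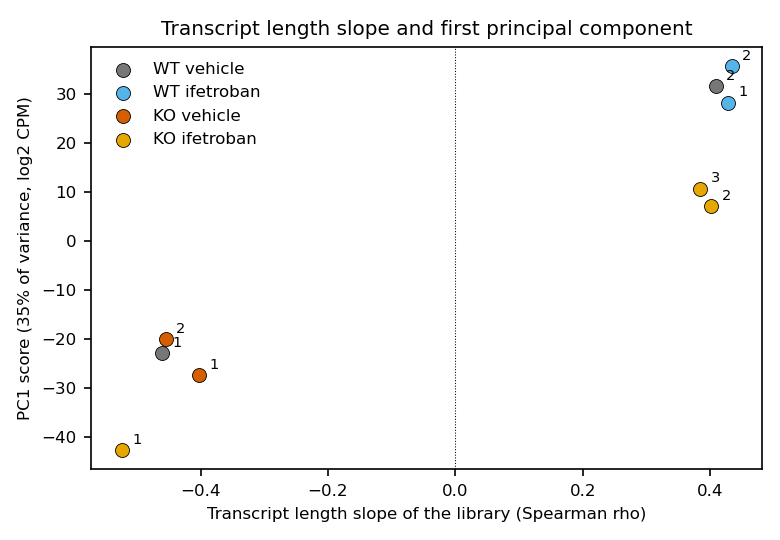
Transcript length slope of each library (Spearman's rho across genes, horizontal axis) against its score on the first principal component of log2 CPM (vertical axis), with points coloured by group and numbered by replicate. The 4 libraries with a negative slope, from -0.52 to -0.40, include 1 labelled WT vehicle, and the 5 with a positive slope lie between 0.38 and 0.43.

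Sgcd (mm10 chromosome 11, 46896253 to 47988969, minus strand, protein-coding) was measured first as the targeted gene. Its level was 8.36 and 20.9 CPM in the libraries labelled WT vehicle replicates 1 and 2, and 23.7 and 23.5 CPM in WT ifetroban. It was 9.64 and 8.63 CPM in KO vehicle and 7.30, 12.9 and 13.3 CPM in KO ifetroban, from 156 to 586 counts per library. The library labelled WT vehicle replicate 1 thus lay within the KO range. Its levels of Pttg1 (64.8 CPM) and Cyfip2 (173 CPM), a pair of genes that separated the other WT from all KO libraries, lay with WT. So did its mean level of the extracellular matrix list, -0.83 on the log2 scale relative to all libraries, against 0.27 to 0.63 in KO. Within each genotype Sgcd was lower in the negative-slope libraries than in the positive-slope ones, with 1 library labelled WT among the former. The Sgcd level thus went with the slope as well as with genotype. KO transcripts were not absent, the deposited value covers the whole gene, and the deleted exons are not given in the sources used here, so the Sgcd level does not check the labels. KO and WT did not differ past the threshold, at a log2 change of -0.90 ± 0.25 (SE) over both treatments (edgeR, adjusted p = 0.101, 5 KO against 4 WT). Within the negative-slope libraries, with 1 labelled WT, the difference was 0.13, and within the positive-slope libraries it was -0.83 (adjusted p = 0.0371). Without the library labelled WT vehicle replicate 1 it was -1.10 (adjusted p = 0.0106).

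The first comparison asked how the KO ventricle differed from WT in mice on plain water. Genes of the extracellular matrix were among those more abundant in KO, as was Ankrd1. This gene, which encodes a stretch-responsive cardiac repressor protein, rose from 734 ± 141 to 2650 ± 141 CPM (SD, n = 2 per group), a log2 change of 1.85 ± 0.19 SE (edgeR, adjusted p = 0.0111). The matricellular protein genes Thbs4 (2.33 ± 0.20) and Postn (2.56 ± 0.33), the latent TGF-beta binding protein gene Ltbp2 (3.17 ± 0.39), the collagen cross-linking enzyme gene Lox (1.73 ± 0.22) and Frzb (1.94 ± 0.21), a secreted Wnt antagonist, also rose, with adjusted p between 0.00556 and 0.0385. Pttg1, which encodes securin, fell by 4.89 ± 0.29 (adjusted p = 2.99e-04), and Cyfip2, a member of the WAVE actin-regulating complex, fell by 2.84 ± 0.27 (adjusted p = 0.00889). These 6 rises and 2 falls were the genes past the threshold, with 1229 genes at an unadjusted p under 0.05 (621 and 777 without KO vehicle replicates 1 and 2, and 2104 without the library labelled WT vehicle replicate 1). The natriuretic peptide genes Nppa (2.09 ± 0.32, adjusted p = 0.0822) and Nppb (1.51 ± 0.32, adjusted p = 0.184), the slow myosin gene Myh7 (1.43 ± 0.49, adjusted p = 0.464) and Tbxa2r (0.89 ± 0.38, adjusted p = 0.592), which encodes the receptor that ifetroban blocks, did not pass.

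These protein-coding genes lie, in mm10, at chromosome 19 36111965 to 36119844 (Ankrd1), chromosome 13 92751590 to 92794818 (Thbs4), chromosome 3 54361109 to 54391037 (Postn), chromosome 12 84783212 to 84876532 (Ltbp2), chromosome 18 52516069 to 52529867 (Lox) and chromosome 2 80411970 to 80447625 (Frzb). Both genes that fell lie near Sgcd on chromosome 11, Pttg1 at 43420250 to 43426251 and Cyfip2 at 46193850 to 46312859. Tbxa2r is at chromosome 10 81328732 to 81335171, Nppa and Nppb are at chromosome 4 148000722 to 148002079 and 147985788 to 147987205, and Myh7 is at chromosome 14 54970688 to 54994634.

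The number of genes past the threshold under vehicle moved with the tool and with single libraries. DESeq2 gave 136 genes, limma-voom 6, a fit without a low-count filter 18, a length and GC offset 33, the split by length slope as a term 118, and the negative-slope libraries alone 290. In that set WT is 1 library, so the spread came from the KO vehicle pair alone. Counting KO ifetroban replicate 1 as vehicle gave 28. Thbs4 (2.11 to 2.52) and Pttg1 (-5.32 to -4.53) passed with each of the 9 libraries left out in turn. The other 6 genes kept their sign but each lost its call without at least 1 library. The count was 4 without the library labelled WT vehicle replicate 1, 2 without KO vehicle replicate 1, 3 without KO vehicle replicate 2, 15 without KO ifetroban replicate 1 and 13 without KO ifetroban replicate 3. Postn and Ltbp2 did not pass with the split as a term, and Lox and Ltbp2 did not pass with limma-voom.

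Of the 26 gene lists tested under vehicle, 11 were higher and 3 lower in KO (camera, preset correlation). The 61 extracellular matrix and fibrosis genes had a median log2 change of 0.96 (adjusted p = 6.02e-74, and adjusted p = 0.0113 with an estimated correlation). Of these genes 4 rose and 57 did not pass, while adjusted over the list alone 47 rose. The 21 cardiac stress and fetal genes shifted by a median of 0.43 (adjusted p = 1.55e-11, and adjusted p = 0.0370 with an estimated correlation), with 1 rise, Ankrd1, and 7 adjusted over the list alone. The 24 genes of the prostanoid pathway shifted by 0.44 (adjusted p = 2.65e-05, and adjusted p = 0.0438 with an estimated correlation), although no member passed, nor did any adjusted over the list alone. Among the list's members, the 5-lipoxygenase activating protein gene Alox5ap, which acts in leukotriene and not prostanoid synthesis, measured 0.81. The phospholipase gene Pla2g4a measured 0.93.

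Immune, stromal and metabolic lists also moved under vehicle, without passing when the correlation was estimated. The 33 macrophage and myeloid markers had a median of 0.87 (adjusted p = 6.35e-25, and adjusted p = 0.0537 with an estimated correlation), with no rise and 19 adjusted over the list alone, and Lgals3 measured 2.55 and Trem2 1.68. The 31 inflammatory cytokine and adhesion genes had a median of 1.04 (adjusted p = 2.18e-12, and adjusted p = 0.137 with an estimated correlation), with 6 rises adjusted over the list alone, and Ccl21a measured 1.12 and Cxcl14 1.04. The 20 fibroblast markers had a median of 0.43 (adjusted p = 1.22e-12, and adjusted p = 0.0537 with an estimated correlation), with 7 rises adjusted over the list alone, and Mgp measured 1.08 and Col1a1 1.06. Lower in KO were the 36 genes of fatty acid oxidation, by a median of -0.28 (adjusted p = 2.55e-08, and adjusted p = 0.137 with an estimated correlation), and the 29 genes of calcium handling and excitation, by -0.31 (adjusted p = 1.67e-06, and adjusted p = 0.206 with an estimated correlation). No member of either passed, and neither did any adjusted over its list alone. Slc27a1, a fatty acid transporter, measured -0.62, Ucp3 -0.64, the potassium channel gene Kcnj3 -0.75 and the sarcoplasmic reticulum gene Hrc -0.47. Medians of markers of other cells were -0.13 for endothelium (adjusted p = 0.235), 0.13 for smooth muscle and pericytes (adjusted p = 0.116) and 0.30 for lymphocytes (adjusted p = 0.191).

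Another 6 lists passed under vehicle with smaller margins, none with an estimated correlation. These were 7 adipocyte markers (median 0.09, adjusted p = 0.0430, and adjusted p = 0.206 with an estimated correlation), 27 interferon response genes (0.13, adjusted p = 0.0120 and 0.509), 27 antioxidant and NRF2 genes (0.14, adjusted p = 0.00175 and 0.407), 24 genes of the unfolded protein and integrated stress response (0.16, adjusted p = 0.00329 and 0.407) and 22 cell cycle genes (0.47, adjusted p = 0.00175 and 0.509), all higher, and 59 nuclear-encoded oxidative phosphorylation genes, lower (-0.13, adjusted p = 0.00304 and 0.728). Their members with the smallest p included Cfd, for which no fold is given because WT vehicle lay at 0 and 0.28 CPM. Car3 measured 2.45, from 0.15 and 0.49 CPM in WT vehicle. The others measured 0.80 for Oas1a, 0.98 for Ifi27l2a, 0.87 for Gpx3, 0.50 for Sod3, 1.19 for Asns and 1.11 for Mthfd2. Mcm5 measured 1.10, Aurka 0.87, Sdha -0.37 and Ndufs1 -0.25. Adjusted over each list alone, 2 adipocyte markers rose and 1 fell, 1 antioxidant gene and 2 unfolded protein genes rose, and no other member passed. Without the library labelled WT vehicle replicate 1 the oxidative phosphorylation list turned to 0.15, and the cell cycle (0.03, with the test turned to lower) and interferon (-0.01) calls were lost. In the negative-slope libraries the test of the unfolded protein list turned to lower (median 0.05). Without WT vehicle replicate 2 the adipocyte (-0.25), antioxidant (-0.05) and unfolded protein (0.04) calls were lost. Leaving out KO vehicle replicate 1 ended the adipocyte (0.17), oxidative phosphorylation (-0.05) and unfolded protein (0.06) calls, leaving out KO vehicle replicate 2 the cell cycle call (0.11), and leaving out KO ifetroban replicate 1 the adipocyte call (0.09).

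Under ifetroban, 4 genes were higher and 2 lower in KO than in WT. Serpina3n, an acute-phase protease inhibitor gene, rose from 12.5 ± 5.79 CPM in WT (SD, n = 2) to 81.9 ± 2.83 CPM in KO (SD, n = 3), a log2 change of 2.71 ± 0.33 SE (edgeR, adjusted p = 0.0367). Lox (2.04 ± 0.20, adjusted p = 0.0125), Ankrd1 (1.57 ± 0.18, adjusted p = 0.0262) and the macrophage protease gene Ctss (1.54 ± 0.18, adjusted p = 0.0331) rose too, and Pttg1 (-4.64 ± 0.24, adjusted p = 1.05e-04) and Cyfip2 (-2.99 ± 0.24, adjusted p = 0.00229) fell. These were the genes past the threshold, with 1455 at an unadjusted p under 0.05 (780 without WT ifetroban replicate 2). Nppa measured 0.99, Nppb 1.35, Myh7 -0.11 and Tbxa2r 0.14, with adjusted p of 0.138 or more. Of the 26 lists, 14 were higher and 5 lower, and 2 passed with an estimated correlation, the extracellular matrix list (median 0.71) and the macrophage list (1.20), each at an adjusted p of 0.0447. In these lists 1 gene each rose, and adjusted over the list alone 23 and 24 did. The count of genes was 290 with DESeq2, 143 with the split as a term, 60 in the positive-slope libraries alone, 58 with a length and GC offset, 19 without a low-count filter and 10 with only the groups compared. It was 11 without the library labelled WT vehicle replicate 1, 10 without WT vehicle replicate 2, 2 without either WT ifetroban library or KO ifetroban replicate 2, and 15 without KO ifetroban replicate 3, with Pttg1 and Cyfip2 passing in every case. Serpina3n (2.30 to 3.28) kept its call only without 1 of the WT vehicle libraries, and lost it without each of the other 7. Ankrd1 (1.45 to 1.70) and Ctss (1.40 to 1.69) lost theirs without either WT ifetroban library, either KO vehicle library or KO ifetroban replicate 2, and Lox (1.95 to 2.14) without either WT ifetroban library or KO ifetroban replicate 2.

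The other 17 lists past the threshold under ifetroban passed with a preset correlation only, with an adjusted p between 0.0640 and 0.572 with an estimated correlation. Higher in KO were the lists of inflammatory genes (median 1.09), erythroid and platelet markers (0.97), mesothelial, nerve and atrial markers (0.90), immediate early genes (0.75), lymphocyte markers (0.73), the unfolded protein response (0.37), cardiac stress (0.35), adipocyte markers (0.34), the prostanoid pathway (0.27), the interferon response (0.25), antioxidant genes (0.17) and fibroblast markers (0.15). Lower were the lists of the cell cycle (-0.46, against 0.47 under vehicle), calcium handling (-0.21), the dystrophin-sarcoglycan complex (-0.21), glucose use (-0.16) and the sarcomere (-0.13). Only Ankrd1, of the cardiac stress list, passed among their members. Adjusted over the list alone 13 inflammatory, 5 cardiac stress, 3 prostanoid, 2 mesothelial, nerve and atrial, 1 lymphocyte and 1 fibroblast gene rose.

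Leaving out 1 library ended 11 of these 17 list calls under ifetroban. Without WT ifetroban replicate 1 the cell cycle list turned (0.14), and the calls of the dystrophin-sarcoglycan complex (-0.21), the sarcomere (-0.13), mesothelial, nerve and atrial markers (0.80) and immediate early genes (0.62) were lost. Without WT ifetroban replicate 2 those of the dystrophin-sarcoglycan complex (-0.21), the sarcomere (-0.16), the interferon response (0.05), glucose use (-0.09) and antioxidant genes (0.16) were lost. Without KO ifetroban replicate 1 those of the dystrophin-sarcoglycan complex (-0.05), calcium handling (-0.10), antioxidant genes (0.04) and immediate early genes (0.42) were lost. Without KO ifetroban replicate 2 those of the sarcomere (-0.12), adipocyte markers (0.36), mesothelial, nerve and atrial markers (0.41) and glucose use (-0.05) were lost. Without KO ifetroban replicate 3 those of fibroblast markers (0.11), mesothelial, nerve and atrial markers (0.82), the interferon response (0.20), glucose use (-0.11) and the cell cycle (-0.41) were lost. The glucose list also lost its call without either WT vehicle library, that labelled replicate 1 (-0.14) or replicate 2 (-0.16), or KO vehicle replicate 1 (-0.14) or 2 (-0.16).

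Over both treatments, with 5 KO against 4 WT libraries and treatment as a term, 321 genes rose and 42 fell in KO (edgeR, adjusted p under 0.05), with 2496 at an unadjusted p under 0.05. The largest rises among the named genes were in Spp1 (osteopontin, 5.05 ± 0.85 SE on the log2 scale), Sprr1a (4.89 ± 0.70), Timp1 (4.08 ± 0.71), a metalloproteinase inhibitor gene, the matrix glycoprotein gene Tnc (3.88 ± 0.47), Cxcl5 (3.25 ± 0.68), Ptx3 (3.12 ± 0.45), Fgr (2.89 ± 0.41) and Gpr39 (2.65 ± 0.38). Tnc averaged 1.48 ± 0.96 CPM in WT (SD, n = 4) and 25.7 ± 18.3 CPM in KO (SD, n = 5). Each of these 8 genes was higher in all 5 KO libraries than in any WT library. WT means were 0.44 CPM for Spp1, 0.25 for Sprr1a, 0.30 for Cxcl5, 0.26 for Ptx3, 0.23 for Fgr and 0.26 for Gpr39. Their folds therefore rest on few WT counts. With a library left out Spp1 ranged from 4.25 to 5.41, Sprr1a from 4.26 to 5.22 and Cxcl5 from 2.56 to 3.72. Spp1 was highest in KO ifetroban replicate 1 (58.0 CPM), the library with conflicting labels, and as low as 2.05 CPM in KO vehicle replicate 2. Pttg1 fell from 47.1 ± 11.8 to 1.70 ± 0.35 CPM (-4.76 ± 0.18, adjusted p = 6.97e-07) and Cyfip2 from 219 ± 31.1 to 29.1 ± 6.71 CPM (-2.92 ± 0.17, adjusted p = 3.22e-05). Other falls were in Sv2c (-2.34), Slc15a2 (-1.59), the chloride channel gene Clcn1 (-1.30), Bcl11b (-1.12), Mme (-0.99) and Lrtm1 (-0.82), each lower in all 5 KO libraries. All 8 genes called under vehicle and all 6 called under ifetroban were among the 363. These comparisons share their libraries, so the overlap is no separate test. Within the negative-slope libraries (genotype under vehicle) and the positive-slope ones (genotype under ifetroban) Ankrd1 measured 1.68 and 1.46, Lox 2.06 and 2.02, Tnc 3.64 and 4.08 and Spp1 4.18 and 4.50, and of these Ankrd1 and Lox passed in the positive-slope libraries and Tnc and Spp1 did not. The negative-slope values rest on 1 library labelled WT, with the spread from the KO vehicle pair alone.

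**Figure D2:**
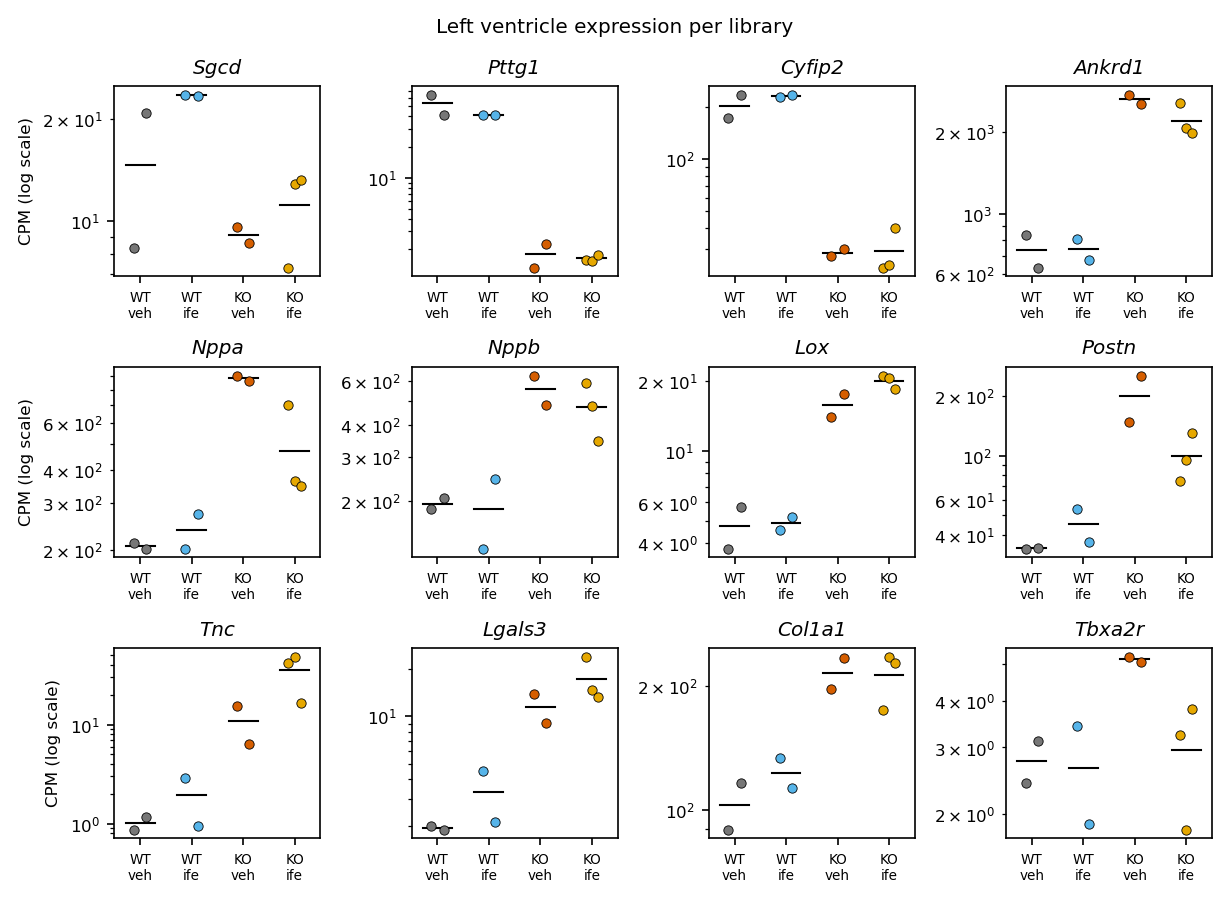
CPM of 12 genes in each library (points, log axis) by group, with the group mean as a line (WT vehicle, WT ifetroban and KO vehicle n = 2, KO ifetroban n = 3). Sgcd in 1 WT vehicle library (8.36 CPM) lies among the KO libraries, whereas Pttg1 stays at or above 40.8 CPM in WT and at or below 2.25 CPM in KO.

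The gene lists described the same contrast. Of the 61 extracellular matrix genes 25 rose and none fell, and adjusted over the list alone 47 rose, with Lox at 1.90 ± 0.15 (adjusted p = 3.31e-04), the connective tissue growth factor gene Ctgf at 1.38 ± 0.13 and Tgfb2 at 1.16 ± 0.11. The list's median was 0.80, and 0.88 with the split as a term, 1.12 in the negative-slope libraries (under vehicle) and 0.78 in the positive-slope ones (under ifetroban). Of the 33 macrophage and myeloid markers 19 rose (median 1.10), and adjusted over the list alone 27 rose and 1 fell, with Lgals3 at 2.45 ± 0.26, Trem2 at 1.65 ± 0.19 and Ctss at 1.32 ± 0.15. The median within the negative-slope and positive-slope libraries was 0.79 and 1.03. Of the 21 cardiac stress genes 5 rose (median 0.39; 8 adjusted over the list alone), among them Ankrd1 (1.70 ± 0.13, adjusted p = 3.24e-04), Gdf15 (1.96 ± 0.26), Nppb (1.42 ± 0.21, adjusted p = 0.00901) and Nppa (1.48 ± 0.27, adjusted p = 0.0217). Of the 24 genes in the prostanoid pathway list 5 rose (median 0.20), and 7 did adjusted over the list alone. Those 5 include the leukotriene synthesis gene Alox5ap (1.02 ± 0.16), the thromboxane synthase gene Tbxas1 (1.02 ± 0.19) and Pla2g4a (0.83 ± 0.17). The receptor gene Tbxa2r did not pass (0.49 ± 0.27, adjusted p = 0.403). These 4 lists passed with a preset correlation, and each had an adjusted p of 0.0129 with an estimated correlation. Within the negative-slope and positive-slope libraries their medians were 0.46 and 0.24 for cardiac stress and 0.48 and 0.27 for the prostanoid pathway.

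A further 12 lists passed over both treatments with a preset correlation only. Of the 31 inflammatory genes 6 rose (median 0.97, adjusted p = 0.0798 with an estimated correlation), such as Icam1 (0.68), Cxcl16 (0.85) and Ccl12 (2.27), and 19 did adjusted over the list alone. Of the 20 fibroblast markers 3 rose (median 0.35, adjusted p = 0.148 with an estimated correlation; 8 adjusted over the list alone), Col1a1 (0.91), Mgp (0.80) and Medag (0.55). Of the 29 genes of calcium handling and excitation 2 fell (median -0.29, adjusted p = 0.219 with an estimated correlation; 4 adjusted over the list alone), Hrc (-0.46) and Kcnj3 (-0.64). Single members rose among lymphocyte markers (Cd52, 1.73; list median 0.49, adjusted p = 0.199 with an estimated correlation), adipocyte markers (Cfd, 2.58; 0.20, adjusted p = 0.141 with an estimated correlation), interferon response genes (Ifi27l2a, 1.15; 0.19, adjusted p = 0.387 with an estimated correlation) and genes of glucose use (Pfkp, 0.49; -0.14, adjusted p = 0.295 with an estimated correlation), although the last list was lower as a whole. Cfd averaged 0.16 CPM in WT, so its fold rests on few counts. Adjusted over each list alone, 1 lymphocyte, 3 adipocyte, 3 interferon and 2 glucose genes rose, and 1 adipocyte and 7 glucose genes fell. Gpx3 (0.69) and Cybb (0.63), which encodes an oxidase subunit, rose in the antioxidant list (median 0.14, adjusted p = 0.295 with an estimated correlation), where adjusted over the list alone 8 genes rose and 1 fell.

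The other 4 lists that passed with a preset correlation had no single member past the threshold, nor any adjusted over the list alone. The unfolded protein list was higher (median 0.34, adjusted p = 0.284 with an estimated correlation), but its test turned to lower in the negative-slope libraries (median 0.05, adjusted p = 0.925, genotype under vehicle), and lower were those of fatty acid oxidation (-0.19, adjusted p = 0.295), the sarcomere (-0.12, adjusted p = 0.265) and the dystrophin-sarcoglycan complex (-0.23, adjusted p = 0.295), each p with an estimated correlation. Their leading members measured 0.80 for Mthfd2, 0.92 for Psat1, -0.29 for Hadh, -0.37 for Acsl1, -0.46 for Myh6, -0.53 for Ttn and -0.24 for Sgca, and the slow myosin gene Myh7 measured 0.56 (adjusted p = 0.532). Ttn differed by 0.90 between the slope sets, and KO held more of the negative-slope libraries than WT. Part of its fall may therefore go with the split. Ttn was 4283 CPM in WT and 3281 to 3832 CPM in KO in the negative-slope set. In the positive-slope set it was 7054 to 7429 CPM in WT and 6212 and 6693 CPM in KO. Medians were -0.06 for endothelial markers, 0.08 for smooth muscle and pericytes, 0.25 for erythroid and platelet markers and 0.22 for mesothelial, nerve and atrial markers, none of which passed. In the calcineurin-NFAT list, which did not pass (-0.06), Rcan1 rose by 0.88. Leaving out 1 library ended the calls of 5 of these smaller lists: the dystrophin-sarcoglycan list without KO ifetroban replicate 1 (-0.16), the sarcomere list without the library labelled WT vehicle replicate 1 (-0.08) or KO vehicle replicate 1 (-0.07), the lymphocyte list without the former (0.55), the interferon list without the former (0.12) or WT ifetroban replicate 2 (0.06), and the glucose list without either of these (-0.11 in both cases), KO vehicle replicate 1 (-0.12) or KO ifetroban replicate 2 (-0.11).

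The size of the genotype effect over both treatments depended on the fit and on single libraries. DESeq2 gave 896 genes, limma-voom 311, the split as a term 472 and a length and GC offset 791, and requiring a 2-fold change left 164. The positive-slope libraries, which compare genotypes under ifetroban, gave 60 genes, of which 45 were among the 363. The negative-slope libraries, which compare them under vehicle, gave 290, of which 103 were, but with 1 library labelled WT, whose Sgcd lay in the KO range, and with the spread from the KO vehicle pair alone. All 363 genes kept their sign in each of these within-set fits, with the split as a term and with the offset. They were called on the same libraries, so agreement in sign was close to given and is no separate test. Fewer genes passed without WT vehicle replicate 2 (186), WT ifetroban replicate 1 (153), WT ifetroban replicate 2 (52), KO vehicle replicate 1 (57), KO vehicle replicate 2 (237) and KO ifetroban replicate 2 (228). Of the 44 genes named as changed here, 13 passed whichever library was left out, namely Tnc, Pttg1, Cyfip2, Sv2c, Nppb, Ankrd1, Gdf15, Lox, Ctgf, Tgfb2, Lgals3, Ctss and Trem2. The other 31 kept their sign and lost the call without at least 1 library, 30 of them without WT ifetroban replicate 2. Tnc, Timp1, Spp1, Nppa and Nppb did not pass with the split as a term.

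**Figure D3:**
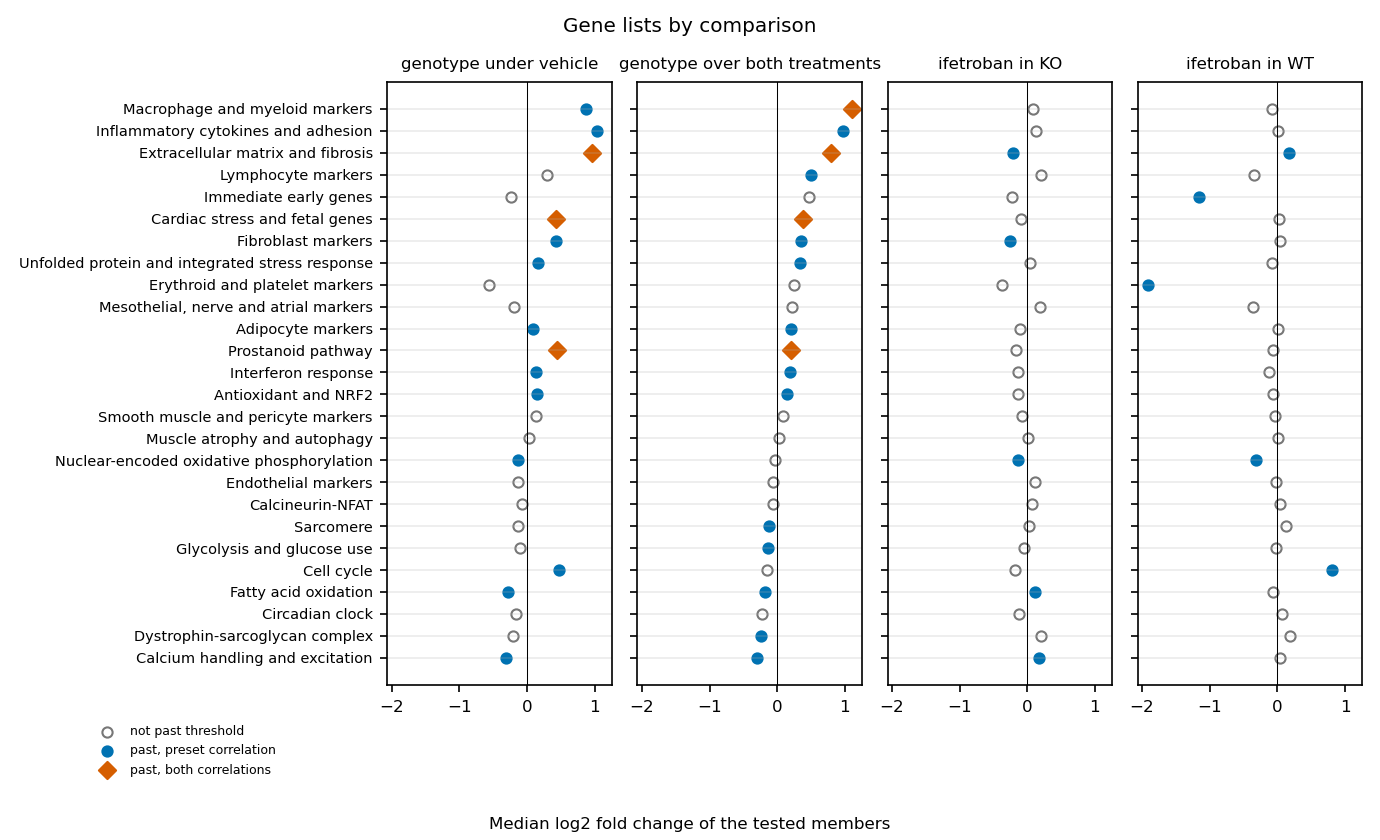
Median log2 fold change of the tested members (horizontal axis) of each of 26 gene lists (vertical axis) in 4 comparisons, with open circles for lists not past the camera threshold, filled circles for those past it with a preset correlation and diamonds for those also past it with an estimated correlation. Diamonds appear for 3 lists under vehicle and 4 over both treatments, and for none with ifetroban in KO or in WT.

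Ifetroban in KO, the question in the series title, was tested with 3 treated against 2 vehicle libraries. No gene passed with edgeR (615 at an unadjusted p under 0.05, smallest adjusted p 0.862), DESeq2 or limma-voom. The count at an unadjusted p under 0.05 was 2274 without KO ifetroban replicate 1, 3451 with that library counted as vehicle, 984 without the library labelled WT vehicle replicate 1, 961 without WT vehicle replicate 2, 373 and 187 without KO vehicle replicates 1 and 2, and 253 without KO ifetroban replicate 2. Without KO ifetroban replicate 1, or with it as vehicle, KO vehicle held only negative-slope libraries and KO ifetroban only positive-slope ones. The counts in these settings therefore cannot set ifetroban apart from the length-slope split. Genes among those with the smallest p were Ucp3 (0.90 ± 0.19 SE), a mitochondrial uncoupling protein gene, Armcx4 (0.84 ± 0.18) and the muscle filamin gene Flnc (0.68 ± 0.16), and, in the other direction, the matrix proteoglycan gene Lum (-0.67 ± 0.15) and Lgi3 (-0.99 ± 0.22). Nppa averaged 884 ± 29.9 CPM in KO vehicle (SD, n = 2) and 472 ± 202 CPM in KO ifetroban (SD, n = 3), with a log2 change of -0.91 ± 0.28, and Tbxa2r measured -0.82 ± 0.33, Nppb -0.23 ± 0.28 and Myh7 -0.57 ± 0.43, all at an adjusted p of 0.862 or more. Myh7 ranged from -1.21 without KO vehicle replicate 1 to 0.59 without KO vehicle replicate 2. The 28 genes past the threshold in the negative-slope libraries are no test of ifetroban, since the treated arm there is KO ifetroban replicate 1, with conflicting labels, and the spread came from the KO vehicle pair alone. No KO vehicle library had a positive slope, so the effect could not be fitted there.

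Among the gene lists, those of the matrix, fibroblasts and oxidative phosphorylation were lower and those of fatty acid oxidation and of calcium handling and excitation higher with ifetroban in KO when the correlation was preset. The 20 fibroblast markers had a median of -0.25 (adjusted p = 5.86e-07, and adjusted p = 0.714 with an estimated correlation) and the 61 extracellular matrix genes of -0.22 (adjusted p = 1.91e-04, and adjusted p = 0.864 with an estimated correlation). Adjusted over the list alone 4 fibroblast markers fell and no matrix gene did, and none passed among all genes. Mgp measured -0.66 and Aspn -0.69. Fatty acid oxidation genes had a median of 0.12 (adjusted p = 0.00201, and adjusted p = 0.864 with an estimated correlation), with 1 rise adjusted over the list alone, and Acot1 measured 1.27. Genes of calcium handling and excitation had a median of 0.17 (adjusted p = 0.0108, and adjusted p = 0.864 with an estimated correlation), and Hcn4 measured 1.07 and Cacnb2 0.37. Oxidative phosphorylation genes had a median of -0.14 (adjusted p = 5.06e-04, and adjusted p = 0.864 with an estimated correlation), and Ndufa6 measured -0.28 and Sdha 0.17. The 3 tested skeletal muscle markers, too few for a list test, had a median of 1.89, and none passed. The matrix call was lost without KO ifetroban replicate 1 (-0.12, adjusted p = 0.0633), the library with conflicting labels, as was that of fatty acid oxidation (0.10, adjusted p = 0.0506). The fibroblast call was kept without it (-0.23, adjusted p = 0.0131) and without each other library. Without KO ifetroban replicate 1, however, ifetroban in KO cannot be told apart from the length-slope split. With that library counted as vehicle the medians were -0.04 for matrix genes (adjusted p = 0.608), -0.18 for fibroblast markers (adjusted p = 0.483) and 0.05 for fatty acid oxidation (adjusted p = 0.277). With the split as a term, and in the negative-slope libraries alone, the oxidative phosphorylation median turned to 0.15 and that of calcium handling was 0.00 and -0.03. The calcium handling call was also lost without KO ifetroban replicate 2 (0.15) or 3 (0.18), and the oxidative phosphorylation call without either of these (-0.07 and -0.04) or KO vehicle replicate 2 (-0.05).

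In WT, ifetroban changed no gene past the threshold with edgeR (350 at an unadjusted p under 0.05, smallest adjusted p 0.881), DESeq2 or limma-voom. The count at an unadjusted p under 0.05 was 2906 without WT vehicle replicate 2, 198 without the library labelled WT vehicle replicate 1 and 659 without KO ifetroban replicate 1. Without WT vehicle replicate 2, a single negative-slope WT vehicle library was set against positive-slope WT ifetroban libraries. That count therefore cannot set ifetroban apart from the length-slope split. The genes with the smallest p were Frzb (1.04 ± 0.22 SE), Epb41l5 (0.66 ± 0.18) and Begain, for which no fold is given because WT vehicle lay at 0 and 0.12 CPM, and Snhg14 (-0.91 ± 0.21), Gstp2 (-1.68 ± 0.41) and Slfn4 (-2.11 ± 0.58). Nppa measured 0.19, Nppb -0.07, Myh7 0.96 and Tbxa2r -0.06. Lists past the threshold with a preset correlation were those of the matrix (0.18, adjusted p = 2.07e-04) and the cell cycle (0.81, adjusted p = 9.77e-09), higher, and of erythroid and platelet markers (-1.91, adjusted p = 4.80e-09), oxidative phosphorylation (-0.32, adjusted p = 8.51e-13) and immediate early genes (-1.16, adjusted p = 4.80e-09), lower. Each had an adjusted p of 0.891 with an estimated correlation, and no member of any passed, nor did any adjusted over its list alone. All 5 calls were lost without the library labelled WT vehicle replicate 1, where the medians were 0.08, 0.27, -0.52, -0.05 and -0.17, the last with the list's test turned to higher.

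The interaction asked whether ifetroban acted differently in KO and WT. No gene passed with edgeR (298 at an unadjusted p under 0.05, smallest adjusted p 1.00), DESeq2 or limma-voom. The count at an unadjusted p under 0.05 was 812 without WT vehicle replicate 2, 147 without KO vehicle replicate 2 and 471 without KO ifetroban replicate 3. Genes with the smallest p were Slfn4 (3.03 ± 0.71 SE), Lgals4 (1.33 ± 0.35), Frzb (-1.41 ± 0.28) and Thbs4 (-1.18 ± 0.27), together with F7 and Kap, for which no fold is given because a group lay at or close to 0 counts. Nppa measured -1.10 ± 0.42, Myh7 -1.54 ± 0.65, Tbxa2r -0.75 ± 0.51 and Nppb -0.17 ± 0.42. With a preset correlation 8 lists passed, 5 higher and 3 lower, and none passed with an estimated correlation.

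Over both genotypes, with 5 ifetroban against 4 vehicle libraries, no gene passed with edgeR (1238 at an unadjusted p under 0.05, smallest adjusted p 0.545) or limma-voom, and 2 did with DESeq2. The count at an unadjusted p under 0.05 was 3448 without KO ifetroban replicate 1 and 3032 without WT vehicle replicate 2, and it was 589 without the library labelled WT vehicle replicate 1, 738 without WT ifetroban replicate 2, 618 and 513 without KO vehicle replicates 1 and 2, and 534 and 640 without KO ifetroban replicates 2 and 3. Without KO ifetroban replicate 1 all ifetroban libraries had a positive slope, and without WT vehicle replicate 2 all vehicle libraries had a negative one. The counts in these settings thus cannot set ifetroban apart from the length-slope split. Genes with the smallest p were Ucp3 (0.75 ± 0.14 SE), Flnc (0.52 ± 0.12) and the stress-induced gene Ddit4 (0.69 ± 0.16), and Rarres2 (-0.52 ± 0.12), Pigp (-0.66 ± 0.17) and Lca5l (-1.08 ± 0.29). Nppa measured -0.42, Nppb -0.16, Myh7 0.10 and Tbxa2r -0.50. Lists lower with ifetroban at a preset correlation were fibroblast (-0.15, adjusted p = 0.00266), erythroid and platelet (-1.01, adjusted p = 4.50e-04), interferon (-0.11, adjusted p = 0.0441), oxidative phosphorylation (-0.22, adjusted p = 4.97e-11) and immediate early genes (-0.63, adjusted p = 4.50e-04), and all had an adjusted p of 0.982 with an estimated correlation. With the split as a term the oxidative phosphorylation list turned to 0.05 and the immediate early list to 0.09, and the test of the erythroid and platelet list turned to higher, with its median at -0.10. The fibroblast call was lost without KO vehicle replicate 2 (-0.15) or KO ifetroban replicate 1 (-0.12), and the erythroid and immediate early calls without the library labelled WT vehicle replicate 1 (-0.43 and -0.21) or KO vehicle replicate 1 (-0.83 and -0.51). The interferon call was lost without WT vehicle replicate 2 (-0.04), WT ifetroban replicate 2 (-0.03), either KO vehicle library (-0.15 and -0.13) or KO ifetroban replicates 1 and 2 (-0.10 in both cases).

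Whether ifetroban moved genes against the knockout was asked across 13436 genes with a mean of at least 1 CPM. The log2 changes of genotype under vehicle and of ifetroban in KO had a covariance of -0.0411 (Pearson's r -0.379, across genes, which are not independent replicates). Both comparisons share the KO vehicle libraries, so unchanged groups simulated against the same libraries gave a mean covariance of -0.0426, from -0.0469 to -0.0390, and a mean r of -0.547. The observed covariance differed from the simulated mean by 0.00151, and 81 of 100 simulations lay at or below it, so no opposition beyond the shared libraries was detected. Without KO ifetroban replicate 1 the difference was -0.0201, with 0 of 100 simulations as low, but r (-0.440) was weaker than the simulated mean (-0.501). With that library counted as vehicle the difference was -0.0459, again with 0 of 100 simulations as low, and r (-0.483) was stronger than the simulated mean (-0.401). In both settings KO vehicle held only negative-slope libraries and KO ifetroban only positive-slope ones. The length-slope split then moves genotype under vehicle and ifetroban in KO in opposite directions. The simulations leave this out, so these differences do not test opposition. The difference was 0.0190 with the split as a term (r -0.423 against -0.649). It was 0.0101 with a length and GC offset (r -0.337 against -0.547), and each was above all 100 simulations. The simulations held no length-slope structure, and their spread came from a fit without the split. The term and the offset remove from the observed values a spread that stays in the simulated ones, so neither difference tests opposition. The same simulated spread limits the other comparisons with the simulations. It was shared by the 4 groups, whereas the KO vehicle pair differed least of all replicate pairs (chi-square per degree of freedom 10.99). The simulated mean covariance of -0.0426 may therefore be too negative, so opposition is not excluded.

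**Figure D4:**
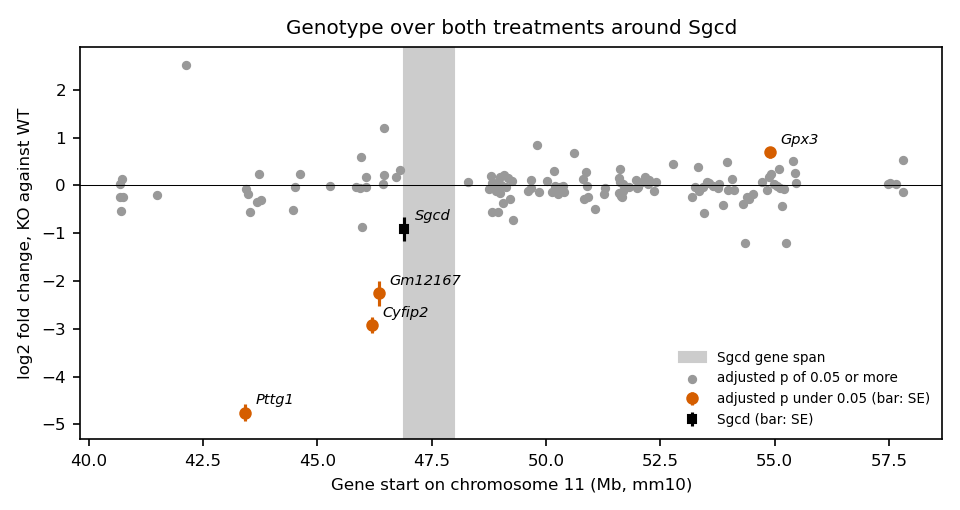
Log2 fold change of KO against WT over both treatments (vertical axis) for the tested genes within 10 Mb of Sgcd, by gene start on mm10 chromosome 11 in Mb (horizontal axis), with bars of 1 SE on Sgcd and on the genes past the threshold. Pttg1 (-4.76), Cyfip2 (-2.92) and the predicted gene Gm12167 (-2.26) lie below the others, and Gpx3 (0.69) lies above 0.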

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

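The tests of the length-slope split, of an estimated correlation and of the fibroblast list without KO ifetroban replicate 1 were chosen after the result was seen for the matrix and fibroblast pattern, as were the estimated correlation for the interaction and the test of strain-derived DNA, and the length-slope split and the length and GC offset are alternatives added after seeing the data. A difference between the genotypes in the effect of ifetroban drew attention to 8 gene lists (camera on the interaction, preset correlation). The difference, KO minus WT, was -0.37 for the extracellular matrix (adjusted p = 4.86e-12), -0.27 for fibroblast markers (2.12e-05), -1.17 for the cell cycle (1.21e-10), 0.12 for macrophage and myeloid markers (0.0160), 1.56 for erythroid and platelet markers (1.64e-05), 0.19 for fatty acid oxidation (2.12e-05), 0.15 for oxidative phosphorylation (0.00338) and 0.99 for immediate early genes (2.12e-05). With an estimated correlation none of the 8 passed, at an adjusted p between 0.542 and 0.944.

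Matrix and fibroblast lists were lower with ifetroban in KO, which could reflect the drug or the libraries, and neither passed with an estimated correlation (adjusted p = 0.864 and 0.714). A length and GC bias as the whole cause is argued against by a matrix median of -0.31 after the offset. With the split as a term that median was -0.29. Both KO vehicle libraries have a negative slope, so this value leans on KO ifetroban replicate 1, the only treated KO library with one. It therefore cannot set the length-slope split apart from that library. KO ifetroban replicate 1, the library with conflicting labels, as the only source is argued against for the fibroblast list at the preset correlation, with a median of -0.23 (adjusted p = 0.0131) without it, though counting it as vehicle ended that call (-0.18, adjusted p = 0.483). Without that library KO vehicle held only negative-slope libraries and KO ifetroban only positive-slope ones. The median without it thus cannot set ifetroban apart from the length-slope split. Shared variation of the list genes between libraries of a group stays possible, with an estimated correlation of 0.122 for the matrix list. That correlation was 0.118 for genotype under vehicle, where the list passed (camera, adjusted p = 0.0113). A missing call therefore does not show this cause. For the matrix list that library cannot be told apart from the drug, because the median without it was -0.12 (adjusted p = 0.0633), so an effect of ifetroban remains open.

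The different effects of ifetroban in WT and KO could likewise come from single libraries. The length-slope split is argued against, as 8 of 8 lists passed in the same direction with it as a term. Shared variation of the list genes stays possible, as 0 of 8 passed with an estimated correlation, though a missing call does not show it. The library labelled WT vehicle replicate 1 alone cannot be told apart from a difference between genotypes, with 4 of 8 lists (matrix, fibroblast, cell cycle and fatty acid oxidation) passing without it, and a difference between genotypes stays open. The other 4 also lost their calls without other libraries, macrophage markers without WT ifetroban replicate 2 (-0.06), KO vehicle replicate 2 (0.01) or KO ifetroban replicate 1 (0.09), erythroid markers without KO vehicle replicate 2 (0.80), immediate early genes without KO vehicle replicate 2 (0.49) or KO ifetroban replicate 1 (0.39), and oxidative phosphorylation without KO vehicle replicate 1 (0.11) or KO ifetroban replicate 1 (-0.00).

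Pttg1 and Cyfip2 fell in every KO library, and a length and GC bias is argued against by a fall of 2.82 or more after the offset (smaller value -2.82). Both lie within 10 Mb of Sgcd, where DNA of another strain could have stayed beside the targeted gene. With the pair left out, 1 of 135 genes there was lower in KO, Gm12167 (-2.26), against 39 of 15411 elsewhere (two-sided Fisher exact test, p = 0.295, genes not being independent replicates). Strain-derived DNA therefore cannot be told apart from an effect of the knockout, since a single gene beyond the pair is too few. The strain of the cells used for targeting is not given in the sources used here.

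For genotype over both treatments, 2 of 100 splits of the libraries into 5 and 4 had at least 363 genes, the real one included. At an unadjusted p under 0.05, 6 of 100 had at least the real 2496 genes. Splits other than the real one were fitted with treatment but without genotype. Genotype differences could therefore widen their spread and lower their counts, so chance is not excluded. The other split with at least 363 genes was the length-slope split, with 4120. The structure of the libraries thus remains beside the genotype effect, and 472 genes passed with the split as a term. Within the sets only genotype under vehicle (negative slope, 290) and genotype under ifetroban (positive slope, 60) could be fitted, not the effect over both. For ifetroban over both genotypes, 100 of 100 splits had as many genes as the real count of 0, an outcome that a count of 0 fixes (highest other 5257, the length-slope split). At an unadjusted p under 0.05, 15 of 100 had at least the real 1238 genes, so chance is not excluded.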

How the results depend on the processing

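The length-slope split, the libraries of each slope alone, the length and GC offset and protein-coding genes only were chosen after seeing the data. The 58 calls of named genes kept their side of the threshold in 1003 of 1276 settings and none turned, and 9 were kept in all. Over all 133 results of named genes, 2566 of 2908 settings gave the same reading, 273 were weaker, 61 stronger and 8 reversed. For list calls 1290 of 1566 were the same, 255 weaker and 21 reversed. Counts of genes stayed within 1.5 times in 112 of 152 settings, and counts of lists in 126 of 152. For each change listed here the cause was not tested, except that subsets hold fewer libraries and a 2-fold minimum keeps fewer genes by construction. Pseudocounts and a filter for normalized values were not run, because the values are counts. Where leaving out a library left 1 in its group, that library was assumed to vary like the other groups.

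Gene counts for genotype under vehicle (8) were 136 with DESeq2, 18 with no low-count filter, 28 with KO ifetroban replicate 1 counted as vehicle, 118 with the split as a term, 290 in negative-slope libraries and 33 with the offset, and 2 to 15 with a library left out. For genotype under ifetroban (6) they were 290 with DESeq2, 19 with no filter, 10 with only the groups compared, 143 with the split, 60 in positive-slope libraries, 58 with the offset and 2 to 15 with a library left out. For genotype over both treatments (363) they were 896 with DESeq2, 60 in positive-slope libraries (the same fit as genotype under ifetroban there), 791 with the offset, 164 at 2-fold or more and 52 to 487 with a library left out. For ifetroban in KO (0) negative-slope libraries gave 28, and for ifetroban over both genotypes (0) DESeq2 gave 2, and negative-slope libraries gave the same 28, since that set fits ifetroban in KO alone. With replicate number as a block the counts were 56 for genotype under vehicle and 172 under ifetroban. They were 550 for genotype over both treatments and 1 for ifetroban in KO. Whether the numbers pair the samples is not settled. Of 12 correlations between samples of the same number (-0.06 to 0.50), 2 exceeded 0.1, both between WT vehicle and KO ifetroban, the groups with libraries of either slope. In groups of 2 libraries the deviations mirror each other, so the 12 are not separate checks.

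Lists past the threshold with an estimated correlation and with fry were 3 and 7 for genotype under vehicle, 2 and 5 under ifetroban, 4 and 8 over both treatments, and 0 and 0 for ifetroban in KO, in WT, over both genotypes and for the interaction. For ifetroban in KO 12 passed with the split and 12 in negative-slope libraries, and 3 to 10 with a library left out. For ifetroban in WT 5 to 8 passed with a library left out. For ifetroban over both genotypes 10 passed with the split, 12 in negative-slope libraries (again ifetroban in KO), 9 with the offset and 2 to 8 with a library left out, and for the interaction 5 passed with KO ifetroban replicate 1 as vehicle. Reversed in the direction of the list test, even where the median kept its sign, in negative-slope libraries were the unfolded protein list under vehicle and over both treatments (0.0462 each), calcium handling with ifetroban in KO (-0.0304, and 0.00382 with the split), oxidative phosphorylation with ifetroban in KO (0.15, and 0.15 with the split) and over both genotypes (0.15, and 0.0463 with the split), erythroid (0.0360, and -0.10 with the split) and immediate early genes (0.30, and 0.0905 with the split) over both genotypes. Oxidative phosphorylation in the interaction was -0.0465 with KO ifetroban replicate 1 as vehicle.

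With a library left out, medians ranged from -0.34 to 0.15 for oxidative phosphorylation and 0.0295 to 1.55 for the cell cycle under vehicle, -1.76 to -0.17 for immediate early genes with ifetroban in WT, -0.0606 to 0.47 for macrophage markers, -0.0767 to 0.39 for oxidative phosphorylation and -0.12 to 1.87 for immediate early genes in the interaction, and -0.88 to 0.14 for the cell cycle under ifetroban. Sgcd ranged from -1.19 to 0.13 under vehicle and Myh7 from -1.21 to 0.59 with ifetroban in KO. In negative-slope libraries Sgcd was 0.13 under vehicle and over both treatments and -0.32 with ifetroban in KO (-0.48 with the split), and Nppb was 0.0924 with ifetroban in KO, while Ndufa6 was 0.0437 with the split. The opposite-effect difference was -0.553 over the 8 called genes, which were selected on the shared KO vehicle libraries while the simulations select none. It was -0.0201 without KO ifetroban replicate 1, -0.0459 with it as vehicle, 0.0190 with the split and 0.0101 with the offset. The simulations held no length-slope structure. The values without that library, with it as vehicle, with the split and with the offset therefore do not test opposition. With 2 or 3 libraries per group, simulated changes of 1 on the log2 scale were recovered in 51% of genes under vehicle, which limits what a missing call shows. The simulated counts held no length-slope structure, so recovery in the data may differ.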

Other observations

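Immediate early genes and erythroid and platelet markers separated single libraries and not groups. The mean level of the immediate early list, relative to its mean over libraries on the log2 scale, was 1.11 in the library labelled WT vehicle replicate 1, 0.98 in KO vehicle replicate 1 and 0.86 in KO ifetroban replicate 1, against -0.96 to -0.01 in the other 6. For erythroid and platelet markers the same 3 libraries had 1.56, 1.22 and 0.79, against -1.28 to 0.10. The cell cycle list was lowest in the library labelled WT vehicle replicate 1 (-1.13) and highest in WT ifetroban replicate 1 (0.84).

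Extracellular matrix genes lay between -0.83 and -0.40 in WT and between 0.27 and 0.63 in KO, and macrophage markers between -0.91 and -0.37 in WT and between 0.28 and 0.67 in KO. Endothelial markers lay between -0.07 and 0.06 in all 9 libraries. The circadian list ranged from -0.44 to 0.34, with no order by group.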
